A study of Mus musculus with 8 samples.

How the data were processed

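RNA from microdissected lung mesenchyme of CD1 mouse embryos was amplified with a 2-cycle cDNA kit, labelled with biotin and hybridised to Affymetrix arrays, per the labels' protocols. The 8 arrays form 4 groups of 2, uncultured tip, uncultured stalk, stalk in control culture and stalk in culture with Wnt1. Nothing in the labels says whether replicates came from separate litters, so p-values measure only the spread between these arrays, which may be technical. For tip, sex-linked genes argue against 2 arrays of 1 RNA sample. Xist was at 991 and 4379 there, and the Y-linked Eif2s3y at 2200 and 263 (replicates 1 and 2). In stalk Xist was at 7275 and 5972, which does not decide it, though heat shock genes differed between its replicates (below). For the culture groups it stays open.

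The deposited values are intensity on a linear scale, 1 per probe set and array, made by the authors with Affymetrix Expression Console and MAS5, per the submitters' processing notes. Versions and settings are not given in the sources used here. The values themselves show a 2% trimmed mean between 499.76 and 499.86 on every array, as a scaling to 500 would give, and the median, which was not fixed by it, ran from 76.5 to 299. Detection calls were not used here, so the highest array median, 298.6, served as a stand-in for the noise floor. On an array with little bright signal, such scaling multiplies the background too, which can make dim genes look higher.

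Of 45101 probe sets, 64 controls were left out. By the platform annotation, 34945 probe sets have 1 gene symbol, 932 have several and 9160 have none. Only those with 1 symbol entered the tests by gene, and 34741 of them matched a gene in the RefSeq table of assembly GRCm38.p6 by gene identifier, with 0 symbols changed. The array files name no genome build, so no coordinates are given. Probe sets above 96.59 (the 40th percentile of all values) on at least 2 arrays were kept, and each gene was represented by its probe set with the highest mean, leaving 16112 genes. Values were tested as log2(value + 44), where 44 is the 25th percentile. Fold changes are on that scale, which understates the change of dim genes.

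All 8 arrays were fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with an intensity trend), without covariates, and 3 comparisons were taken, tip minus stalk, Wnt1 minus control culture and control culture minus stalk. Tests were two-sided, with Benjamini-Hochberg adjustment over genes and a threshold of 0.05. The 20 gene lists, 13 of pathways and 7 of cell types, were tested with camera (preset correlation 0.01, or estimated) and fry, adjusted over the 20 lists in each comparison. With 2 arrays against 2 there are 3 splits, so an exact permutation test could not give a p below 0.33 and none was run. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

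Groups, tests, gene lists, most alternatives and the rule for named genes were set before the data were examined. The rule names, per comparison and direction, the 10 genes with the largest log2 fold change among those past the threshold whose replicates do not overlap, leaving out predicted and clone-named genes. Where fewer than 5 pass, genes with the smallest p at 2-fold or more and without overlap fill up to 5 and are stated as not past the threshold. From each list it takes up to 4 members past the threshold by p, or the 2 largest changes as values, and always Axin2, Lef1, Fgf10, Wnt2, Acta2, Myh11 and Mki67. The genes Myocd, Xist and Eif2s3y, and Fos in the uncultured arrays, were named outside this rule after their values were seen.

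The test was tried on simulated data with the noise of each group, in 5 runs with 200 of 16112 genes changed. Of 100 genes changed 2-fold, it recovered 0.2% for tip minus stalk, 4% for Wnt1 minus control culture and 0.8% for control culture minus stalk. Of 100 changed 4-fold, it recovered 24.2%, 34.4% and 33.2%. Unchanged genes made up 0%, 22.3% and 1.73% of the calls in the same order, so the shared spread is too small for the Wnt1 comparison and too large for tip against stalk. Simulated lists of 15 genes shifted by 0.5 had an unadjusted camera p under 0.05 in 100%, 79% and 97% of cases, and unshifted lists in 4%, 0% and 4%, with noise drawn independently between genes. In the real control culture minus stalk, 4179 genes passed, far more than the 200 changed in a run. As the adjustment depends on the share of changed genes, 0.8% and 33.2% do not measure recovery in that comparison.

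The 26 alternatives changed the pseudocount, the filter, the normalization, the variance model, the treatment of probe sets, the threshold, the arrays used and the replicate block, with the 2 other list tests. They include 3 added after the data were seen, a signal floor at the highest array median, array quality weights, and a fit without both culture arrays numbered 1. The floor ties dim values and the spread was estimated anew with it, so a call could change without its fold change. Passing or failing with the floor is therefore not by itself a measure of noise.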

Results

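Gene expression was measured on 8 arrays of mesenchyme, the connective tissue around the branching airway, microdissected from the lungs of CD1 mouse embryos. There were 4 groups of 2 arrays. Tip mesenchyme, from around the growing ends of the branches, and stalk mesenchyme, from around the airway behind them, were profiled directly after dissection. Further stalk pieces were kept for 12 h on culture plastic, either in control medium or with 400 ng/ml of the secreted signalling protein Wnt1. The design addresses how tip and stalk differ and how stalk responds to Wnt1, and the uncultured stalk allows a comparison of stalk with and without culture. The number of arrays, 2 per group, limits the precision of every value below.

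The culture arrays stood apart in their technical measures. Their median signal was 149 to 299, against 76.5 to 99.8 on the uncultured arrays, although all 8 arrays had a 2% trimmed mean of about 500. The hybridisation controls, transcripts added to every sample, were 2.78 to 10.8 times the mean of the uncultured arrays after this scaling. The 3' to 5' signal ratio of Actb, a measure of RNA integrity and labelling length, was 6.81 to 24.4 in culture and 2.02 to 4.52 without it. Replicates correlated at 0.974 for tip and 0.975 for stalk, but at 0.828 for control culture and 0.837 for Wnt1 culture (Pearson, across genes, which are not independent replicates). Some arrays of different groups were closer than replicates. Tip replicate 2 and stalk replicate 1 correlated at 0.978, and the other pairs of tip and stalk arrays at 0.972 to 0.973. Control and Wnt1 culture replicates 2 correlated at 0.912, and the other pairs of control and Wnt1 arrays at 0.819 to 0.830.

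**Figure D1:**
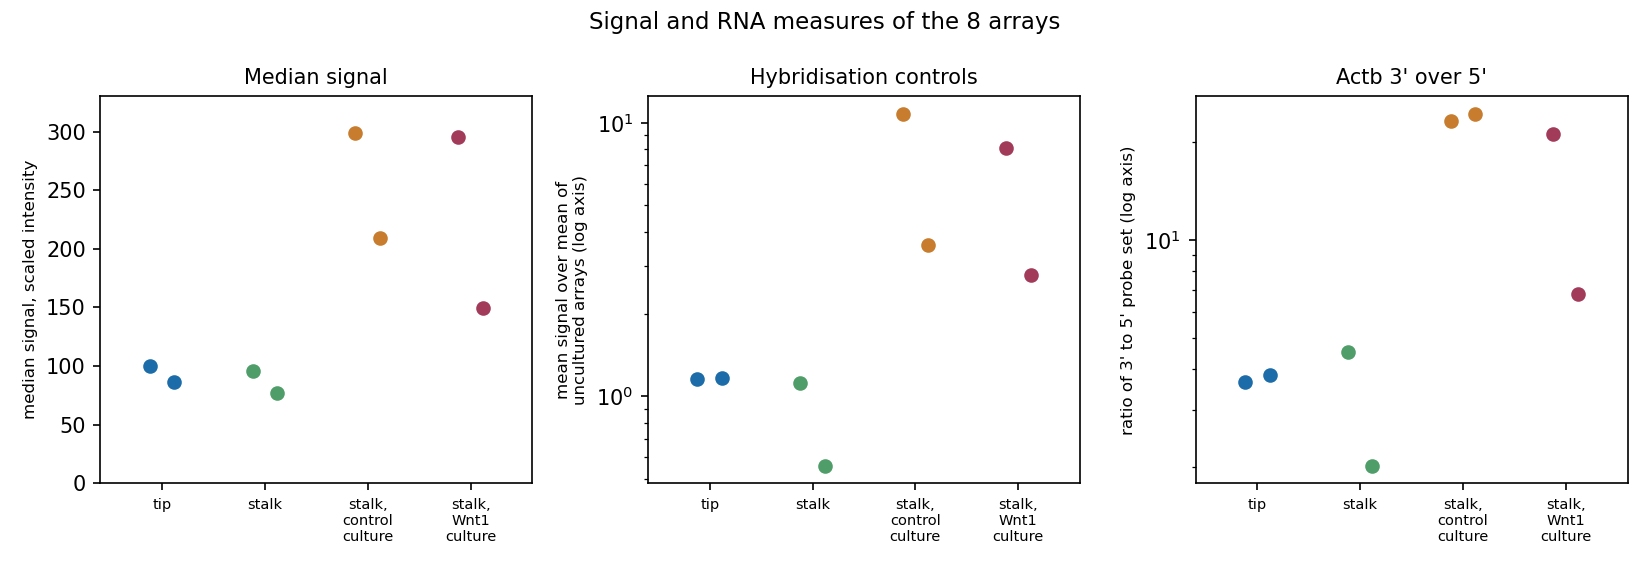
Median scaled intensity, hybridisation controls relative to the mean of the uncultured arrays, and the 3' to 5' ratio of Actb, with 1 point per array and 2 arrays per group; the last 2 panels have log axes. The control culture arrays lie at medians of 299 and 209 and the uncultured arrays at 76.5 to 99.8.

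Tip mesenchyme had lower levels of smooth muscle contractile genes than stalk. In this list, 14 of 15 members had a negative log2 fold change (tip minus stalk), and the median was -0.56. Acta2, the smooth muscle actin, had a signal of 1980 ± 1669 in tip and 3889 ± 803 in stalk (SD, n = 2; log2 fold change -1.24 ± 0.55, SE), but its change was 0.90 when probe sets with the suffixes _x_at and _s_at were left out. The changes of Actg2, another smooth muscle actin, and Myocd, a transcriptional activator of smooth muscle genes, were -1.26 ± 0.48 and -0.99. Extracellular matrix genes were also lower in tip, 20 of 22 of them with a negative change and a median of -0.38, among them the collagen chain Col6a3 at -1.07 ± 0.53. As lists, both differed from the other genes by camera with a preset correlation of 0.01 (adjusted p = 6.0e-09 and 3.7e-07). Both calls were lost with an estimated correlation (adjusted p = 0.28) and with fry (adjusted p = 0.70). Only 8 of the 15 smooth muscle genes exceeded the highest array median, that of a culture array, in either group. With values below it raised to it, a signal floor added after the data were seen, the smooth muscle median was -0.02 (camera, adjusted p = 0.018) and the matrix median -0.37. The tip and stalk arrays had medians of only 76.5 to 99.8. A tip and stalk difference that shrinks with this floor, here or below, is therefore not shown to be noise.

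Markers of other cell types differed between tip and stalk as well. Endothelial markers were lower in tip (13 of 14 members, median -0.48, adjusted p = 5.5e-07), including Sox17 at -1.49 ± 0.57. The macrophage list was lower with a median of -0.65 (11 of 11 members, of which 5 exceeded the floor in either group, adjusted p = 3.6e-07), and the erythroid list with a median of -0.53 (6 of 7 members, adjusted p = 0.0016), with Slc4a1 at -0.86 ± 0.37. Markers of mesothelium, the outer lining of the lung, were higher in tip (8 of 9 members, median 0.40, adjusted p = 9.5e-06), with Bnc1 at 1.04 ± 0.45 and Upk3b at 0.79 ± 0.34. Each of these calls was lost with an estimated correlation (adjusted p = 0.28) and with fry (adjusted p = 0.70). The macrophage and mesothelial calls were also lost without tip replicate 1, at adjusted p = 0.64 and 0.17, the macrophage median then being 0.04, and the erythroid call without stalk replicate 1, at 0.10. With the signal floor the macrophage median was 0 (adjusted p = 0.17).

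Signalling genes gave smaller differences. The Bmp and Tgf-beta list had a median of 0.23 (adjusted p = 0.049, and 0.28 with an estimated correlation), with Grem1, a Bmp antagonist, at 1.08 ± 0.42 (0.04 with the signal floor), but missed the threshold in 20 of 24 alternatives. Fgf10, a growth factor of distal lung mesenchyme, had a signal of 331 ± 145 in tip and 150 ± 23 in stalk (SD, n = 2; 0.90 ± 0.55, SE, and 0.24 with the signal floor). Both means lay above the medians of the tip and stalk arrays, 76.5 to 99.8. The Fgf list as a whole had a median of 0.24 (adjusted p = 0.17). Wnt/beta-catenin targets had a median of 0.16 and hedgehog signalling -0.18 (adjusted p = 0.090 for both), with Axin2 at -0.20 ± 0.40 and Lef1 at 0.41 ± 0.41. Wnt2 had a change of 0.35 ± 0.52, Myh11, a smooth muscle myosin, of -0.92 ± 0.53 (0 with the signal floor), and Mki67, a proliferation marker, of -0.58 ± 0.47. The adjusted p was 0.090 for epithelium, 0.094 for hypoxia and glycolysis (0.0081 with quantile normalization), 0.17 for immediate early and stress genes and 0.19 for cartilage genes. It was 0.63 or higher for the other 6 lists, which hold Wnt ligands, lung mesenchyme transcription factors, cell cycle, Yap targets, neurons and pericytes. For Wnt ligands, cell cycle and neurons the medians lay just below 0 while the test pointed up.

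No single gene of 16112 passed the threshold between tip and stalk (limma, adjusted p under 0.05; smallest adjusted p = 0.99992). None did when adjusted over the list alone, in any of the 20 lists. At an unadjusted p under 0.05 there were 96 genes, where 806 would be reached by chance, and 865 when only the tip and stalk arrays entered the fit. The fit shares its spread with the more variable culture arrays. The genes with the smallest p among those changed at least 2-fold without overlap of replicates were Wbp2nl, Fam170b, Art1, Lrrc51 and Col4a4 on the higher side. On the lower side they were Slc5a3 (-1.10 ± 0.36), Klf12, Ptprb, B3gntl1 and Inava, and none of the 10 passed the threshold. In the first 4 and in B3gntl1 both groups lay under the signal floor, and Col4a4 and Inava were at 0.31 and -0.16 with it. Groups without overlap occurred in 34.5% of genes, against 33.3% by chance. Across genes, the differences of the 2 array pairs correlated at -0.019 by number and 0.068 when crossed. Immediate early and heat shock genes separated tip replicate 1 and stalk replicate 2 from the other uncultured arrays. The immediate early list, with a median of -0.22, had medians of 0.48 and 0.71 without tip or stalk replicate 2, and of -0.81 and -1.29 without tip or stalk replicate 1. The difference was therefore also taken within each of these array pairs. The list medians of tip replicate 1 minus stalk replicate 2 and of tip replicate 2 minus stalk replicate 1 were -0.66 and -0.16 for smooth muscle and -0.39 and -0.32 for matrix. They were -0.79 and -0.13 for endothelium, 0.77 and 0.17 for mesothelium, and 0.24 and 0.16 for Bmp and Tgf-beta signalling. For macrophages they were -0.88 and 0.01, and for erythroid cells -0.02 and -0.74.

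No rise of Wnt pathway targets as a group was found with Wnt1 in cultured stalk. The 16 measured Wnt/beta-catenin targets had a median log2 fold change (Wnt1 minus control culture) of -0.38, with 5 above and 11 below 0, and the list was not called against the other genes (camera, adjusted p = 0.34). Across genes, the Wnt1 differences of the 2 array pairs taken by number correlated at only 0.034. An absent response and a missed one therefore cannot be told apart. Axin2, a direct target and feedback inhibitor, had a signal of 372 ± 158 with Wnt1 and 260 ± 24 without (SD, n = 2; 0.40 ± 0.40, SE), with alternatives from -0.08 to 0.82. Lef1, a transcription factor of the pathway, was at -0.69 ± 0.41, with alternatives from -1.23 to -0.03. Notum, a secreted inhibitor, was at -1.09 ± 0.48, and at -0.28 with the signal floor, where it passed (limma, adjusted p = 0.020). Wnt2 was at -0.74 ± 0.52 (0.15 without control replicate 1), Fgf10 at -0.27 ± 0.55 (-1.11 to 0.56 over the alternatives) and Mki67 at -0.92 ± 0.47.

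Smooth muscle contractile genes were higher with Wnt1 in the list test (12 of 15 members above 0, median 0.35, adjusted p = 0.025, and 0.79 with an estimated correlation). Tpm1, a tropomyosin, was at 1.20 ± 0.39 and Tagln, an actin-binding protein, at 1.14 ± 0.45. Acta2 was at 0.27 ± 0.55 (-1.28 without _x_at and _s_at probe sets) and Myh11 at 0.14 ± 0.53 (-0.54 with the signal floor). The call was lost in 11 of 24 alternatives, and without Wnt1 replicate 2 the list median was 0.06 (adjusted p = 0.99). That array had an Actb 3' to 5' ratio of 6.81 and a median of 149, against 21.2 to 24.4 and 209 to 299 on the other 3 culture arrays. Extracellular matrix genes had a median of -0.48 (20 of 22 below 0, adjusted p = 0.070) and passed in 11 of 24 alternatives, but the median was 0.21 between the culture arrays numbered 1 and -0.96 between those numbered 2. Members with large changes were Mfap4 at -1.88 ± 0.64 and Col6a2 at -1.85 ± 0.53. The other 18 lists had adjusted p = 0.16 or higher by camera. By fry, the 7 pericyte markers had an adjusted p = 0.047 (median -0.52), with medians of -0.22 and -0.83 between the culture arrays numbered 1 and 2. Cspg4 was at -2.33 ± 0.53, and at -0.11 with the signal floor.

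No single gene passed the threshold between Wnt1 and control culture. At an unadjusted p under 0.05 there were 1311 genes (limma), where 806 would be reached by chance, but 400 when only these 2 groups entered the fit. Groups without overlap occurred in 26.2% of genes, against 33.3% by chance. The smallest adjusted p was 0.098, for Adamts20, a secreted protease, with signals of 13.3 ± 8.34 with Wnt1 and 413 ± 172 without (SD, n = 2; -2.95 ± 0.40, SE). As the signal with Wnt1 lay under the floor, the size of this change is uncertain, and it was -0.38 with the signal floor (adjusted p = 0.69). After Adamts20 on the lower side came Sox9 (-2.46 ± 0.48), a cartilage transcription factor, Ccpg1, Adat1 and Lrrn1, and on the higher side Glipr2 (2.56 ± 0.45), Tax1bp3, Nt5dc1, Zfp423 and Tsc2, each with an adjusted p = 0.54. With the signal floor several of these shrank, to -0.51 for Sox9, -0.33 for Lrrn1, 0.49 for Nt5dc1, 0.21 for Tsc2 and 0.13 for Zfp423, while Glipr2 was at 1.65 and Tax1bp3 at 1.77. Adjusted over the list alone, 2 genes passed, 1 cartilage and 1 pericyte gene, both lower. Leaving out control replicate 2 gave 56 genes and leaving out Wnt1 replicate 2 gave 25, and without both culture arrays numbered 1, an alternative added after the data were seen, 799 genes passed with the spread taken from the uncultured arrays alone. Across genes, the difference between the arrays numbered 1 correlated at 0.034 with that between the arrays numbered 2, and at -0.27 when the numbers were crossed, compared with 0.70 and 0.66 for control culture against stalk.

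The tip and stalk differences were set against the Wnt1 response, which comes from other arrays. The 83 genes at least 2-fold higher in tip, or the 100 higher in stalk, were taken by the smallest unadjusted p, since too few passed the threshold. Between tip and stalk 96 genes had an unadjusted p under 0.05 (limma), or 865 with these arrays alone, where chance gives 806. The sets may therefore hold mostly noise, and a median near 0 does not show that Wnt1 leaves tip or stalk genes unchanged. With the signal floor they held 9 and 18 genes. The tip-high genes had a median Wnt1 response of -0.03 (camera, adjusted p = 0.73 over the 2 sets) and the stalk-high genes of -0.28 (adjusted p = 0.22). Across the 16112 genes the fold changes of the 2 comparisons correlated at r = 0.009 (Pearson) and 0.018 (Spearman), with genes not being independent replicates. The tip-high median turned with the arrays used, being 0.31 without control replicate 1 and 0.34 without Wnt1 replicate 2, but -0.35 without control replicate 2 and -0.48 without Wnt1 replicate 1.

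**Figure D2:**
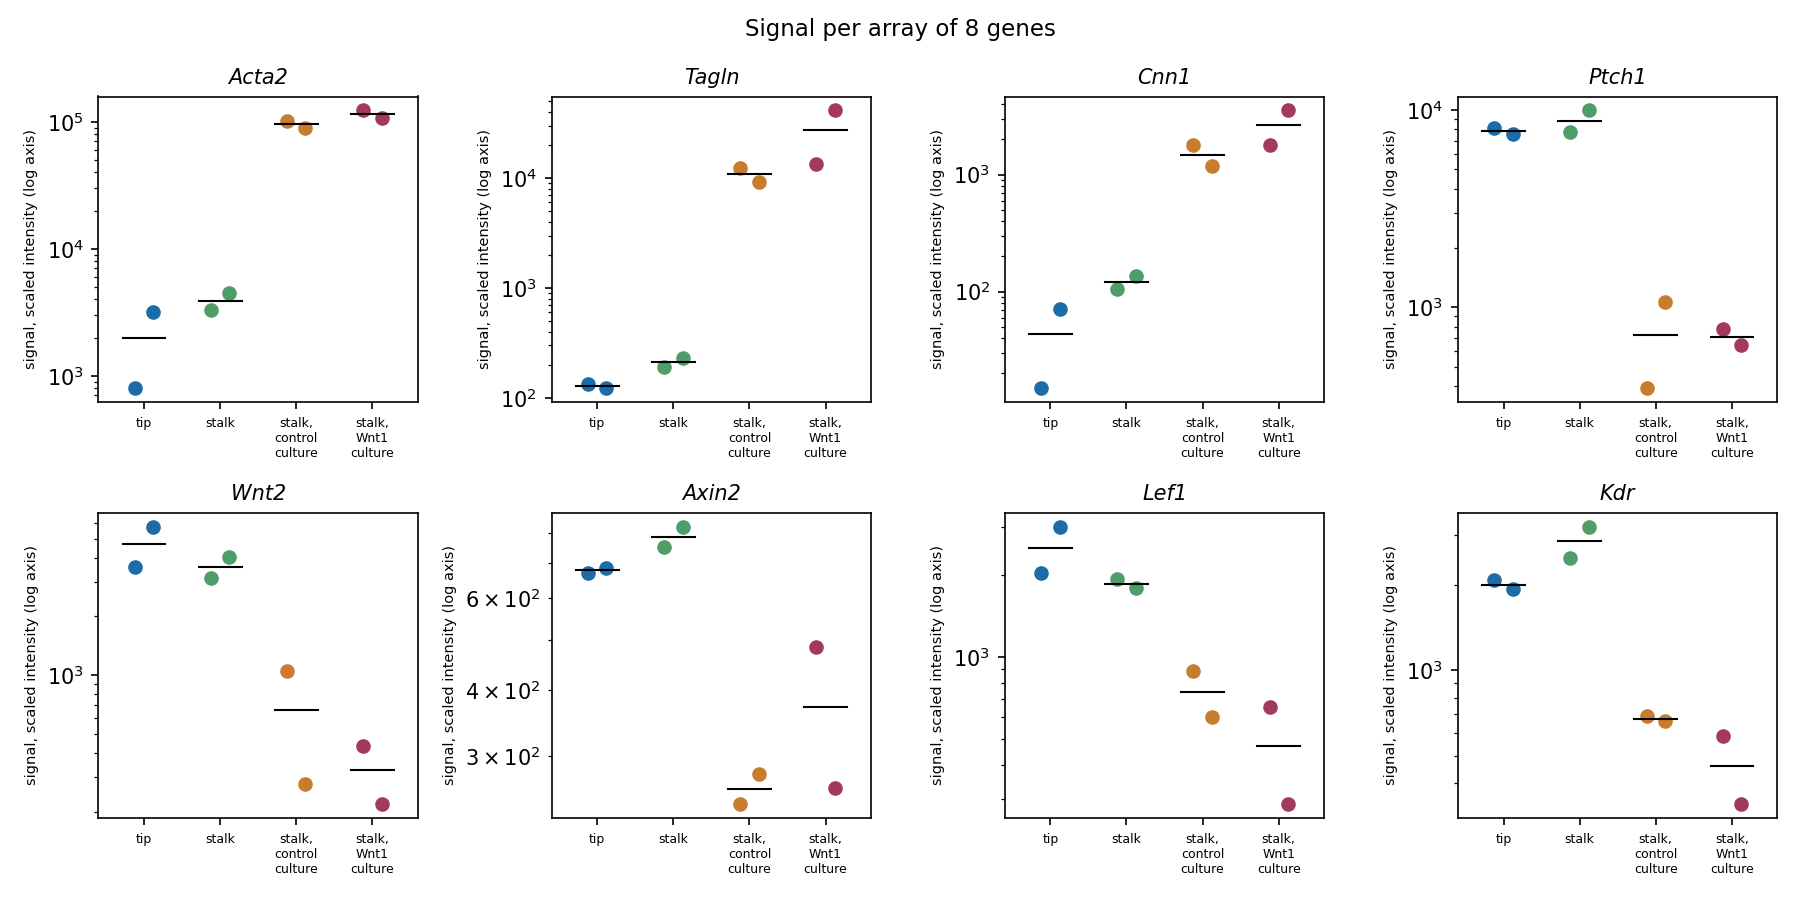
Scaled intensity per array of 8 genes on log axes, with 1 point per array, 2 arrays per group and a line at the group mean. Acta2 lies at 95427 on average in control culture and at 3889 in uncultured stalk, while Ptch1 lies at 727 and 8836.

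Smooth muscle contractile genes were higher in stalk mesenchyme after control culture than in uncultured stalk. Of 15 members, 8 rose and none fell past the threshold (10 rose when adjusted over the list alone). Acta2 went from 3889 ± 803 to 95427 ± 9044 (SD, n = 2; log2 fold change 4.61 ± 0.55, SE, adjusted p = 0.0014), a change of 2.53 without _x_at and _s_at probe sets. Tagln had the largest rise of the genes that passed, from 211 ± 31 to 10803 ± 2117 (5.40 ± 0.45, adjusted p = 0.00038), and Actg2 (3.97 ± 0.48) and the actin-binding protein Cnn1 (3.19 ± 0.48) rose too. Myh11, at 1.47 ± 0.53, missed the threshold (adjusted p = 0.056), and Myocd was at -0.41. The list median of 2.01 lay above the median of all genes, 0.43 (camera, adjusted p = 0.0017, and 0.41 with an estimated correlation). The Yap and serum response genes Ankrd1 (4.50 ± 0.49), Ccn2 (3.38 ± 0.68) and Thbs1 rose, Ajuba fell by 2.50, and the list had an adjusted p = 0.86.

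Genes of hedgehog signalling fell, 5 of 10 members, with a list median of -1.27 (adjusted p = 0.00025, and 0.26 with an estimated correlation). Ptch1, the hedgehog receptor and a target of the pathway, fell by 3.67 (SE 0.41) on the log2 scale, from 8836 ± 1574 to 727 ± 475 (SD, n = 2), although its other probe set moved the opposite way. Gli1, the transcription factor induced by the pathway, was at -2.11 ± 0.55, with Smo at -1.54 ± 0.34 and Gli3 at -1.42 ± 0.33. Of 16 Wnt/beta-catenin targets, 7 fell and 1 rose (median -0.25, or -0.69 relative to all genes, adjusted p = 0.013, and 0.31 with an estimated correlation). Tnfrsf19 was at -3.11 ± 0.40, Axin2 at -1.45 ± 0.40 (adjusted p = 0.024) and Lef1 at -1.30 ± 0.41 (adjusted p = 0.036), while Lgr5 rose by 2.79 ± 0.56. With the signal floor Lgr5 was at 0.37, Axin2 at -1.27 and Lef1 at -1.30, and none of these passed, whereas Tnfrsf19, at -2.96, did. This list's call was lost with the mean of a gene's probe sets (median 0.21, adjusted p = 0.14) and without control replicate 2 (0.052). Among Wnt ligands and their partners 3 rose, including Wnt4 (3.83 ± 0.48) and Wnt5a (1.93 ± 0.44), and 4 fell, including Wnt2 (-2.60 ± 0.52) and Rspo2 (-1.56 ± 0.35). Adjusted over the list alone the counts were 4 and 4, and the list had a camera adjusted p = 0.51. With the signal floor Wnt4 was at 1.26, Wnt5a at 0.99, Wnt2 at -2.56 and Rspo2 at -1.56, and of these only Wnt5a passed. Rspo2 lost its call at an unchanged fold change (limma, adjusted p = 0.013 without the floor and 0.064 with it).

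Lung mesenchyme transcription factors fell in 6 of 20 members and rose in 1 (median -0.58, adjusted p = 0.00091, and 0.26 with an estimated correlation). Tbx4 and Tbx5, T-box factors of the lung field, were at -2.19 ± 0.32 and -1.89 ± 0.39, and Tcf21 was at -1.44 ± 0.35. With the mean of a gene's probe sets, Tcf21, Meis1 and Rspo2 had changes of the opposite sign. Cell cycle genes fell in 10 of 22 members (13 when adjusted over the list alone; median -1.05, adjusted p = 1.2e-07, 0.38 with an estimated correlation and 0.060 with fry). Aurkb, a mitotic kinase, was at -2.33 ± 0.34 and Bub1 at -2.05 ± 0.34, whereas Mki67 missed the threshold (-1.33 ± 0.47, adjusted p = 0.053). The other lists called by camera in this comparison, here and below, passed with fry (adjusted p = 0.027 to 0.045). That test does not set a list against the other genes.

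Markers of other cell types also differed between control culture and uncultured stalk. Endothelial markers fell in 8 of 14 members (9 when adjusted over the list alone; median -1.85, adjusted p = 3.6e-06, and 0.26 with an estimated correlation), among them Sox17 (-3.49 ± 0.57), Sox18 (-3.28 ± 0.55) and Kdr, the main Vegf receptor (-1.99 ± 0.35). Erythroid genes fell in 4 of 7 members (adjusted p = 0.0042, and 0.26 with an estimated correlation), with the globin Hba-x at -2.87 ± 0.46, while the globin Hbb-y rose by 2.53 ± 0.69. The erythroid call was lost without control replicate 2 (adjusted p = 0.051). Epithelial markers rose in 6 of 18 members (7 when adjusted over the list alone; median 1.44, adjusted p = 0.0042, and 0.38 with an estimated correlation), with Epcam at 2.33 ± 0.39 and Krt19 at 1.56 ± 0.38. That call was lost with a signal floor at the highest array median (adjusted p = 0.065) and without control replicate 2 (0.051), and Epcam and Hbb-y changed sign when probe sets with the suffixes _x_at and _s_at were left out. The macrophage genes C1qb, Tyrobp (1.95 ± 0.39), Lyz2 and C1qc rose, 4 of 11 (5 higher and 1 lower when adjusted over the list alone), with an adjusted p = 0.068 for the list, which passed with the signal floor (adjusted p = 0.0052). Of mesothelial and neural markers 2 each rose (adjusted p = 0.28 and 0.068), and of 7 pericyte markers none passed.

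The remaining lists did not differ from the other genes (adjusted p = 0.49 or higher), although members of each changed. In every list of this comparison for which no count adjusted over the list alone is given, it equalled the count over all genes. With quantile normalization the matrix and Yap lists passed (adjusted p = 0.0088 and 0.037), and with array medians centred the neural list did (0.046). Of 14 Fgf genes 4 rose (5 when adjusted over the list alone), Fgfr4, Fgf10 (1.81 ± 0.55, adjusted p = 0.033), Fgf18 and Etv4. In the Bmp and Tgf-beta list 4 rose, including the antagonists Grem1 (2.55 ± 0.42) and Fst (2.27 ± 0.48), and 2 fell (3 when adjusted over the list alone). Among 22 matrix genes 6 rose, including Tnc (2.63 ± 0.47) and Postn, and Vcan fell by 2.90. In the cartilage list 2 rose and 1 fell. The hypoxia genes Adm and Car9 rose, and of the immediate early genes Ier3 rose, but not when adjusted over the list alone. The medians of Wnt ligands, hypoxia, immediate early and pericyte genes were above 0 while the test, relative to all genes, pointed down.

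**Figure D3:**
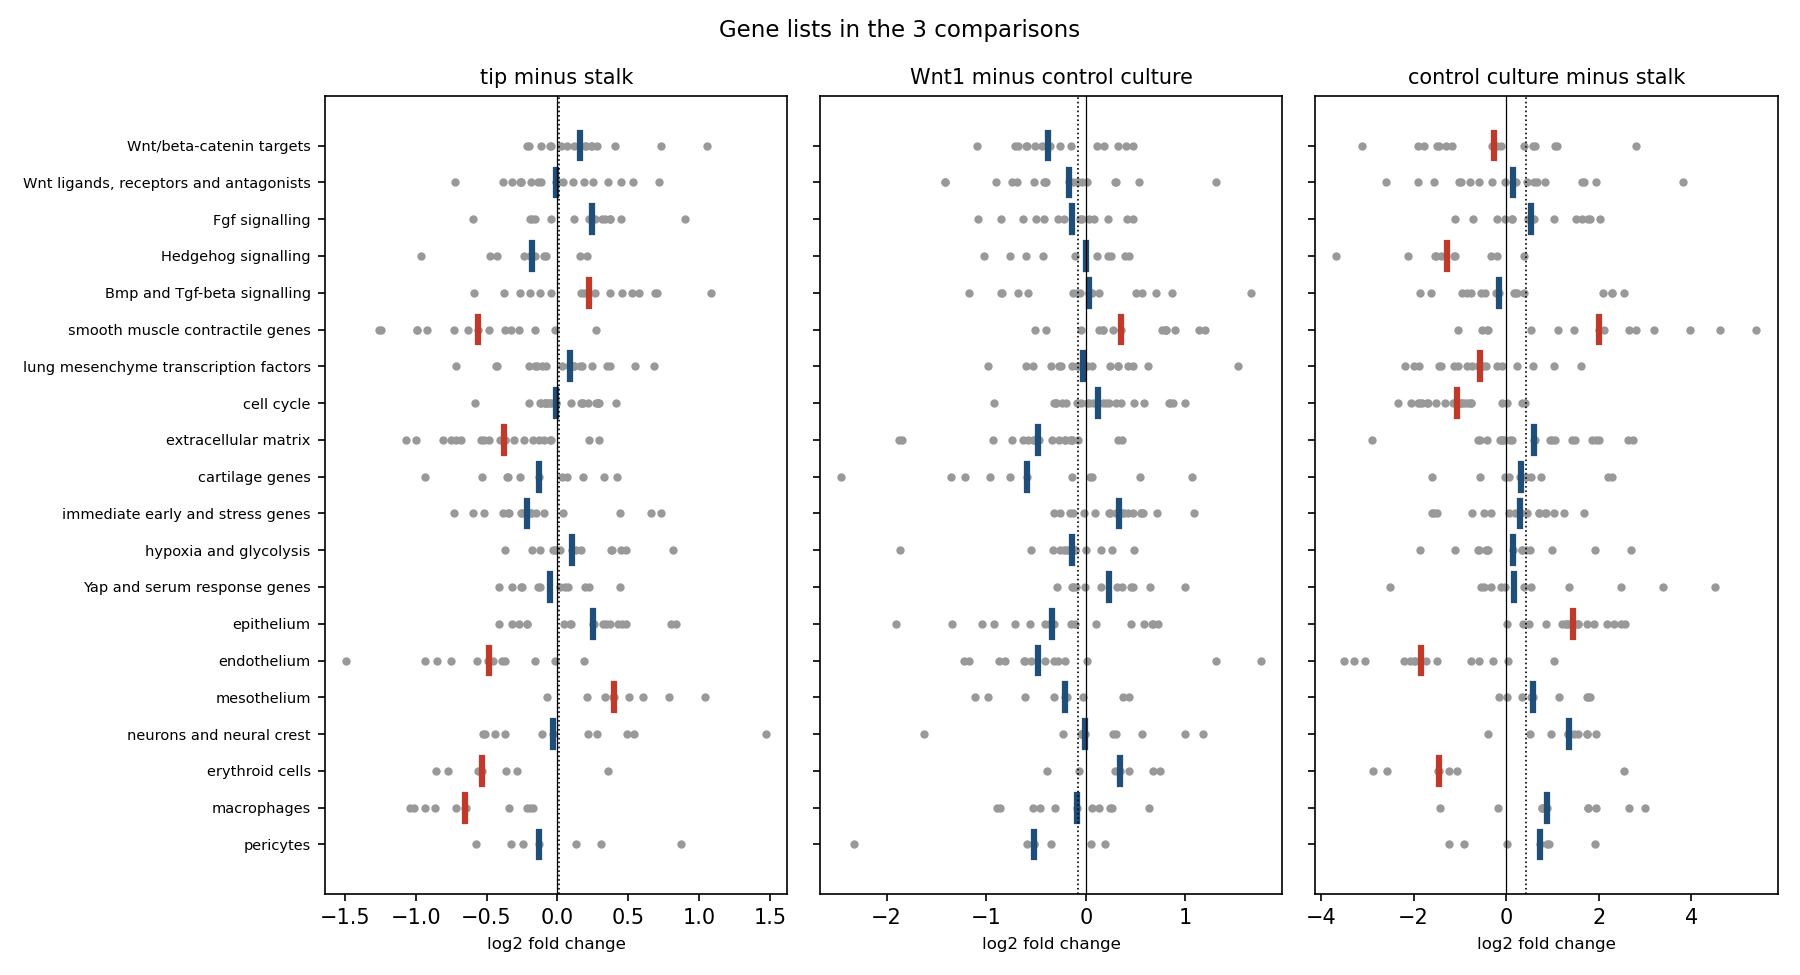
Log2 fold changes of the 20 gene lists in the 3 comparisons, each panel with its own axis; grey points are genes, thick bars list medians, red where the camera adjusted p is under 0.05, and the dotted line is the median of all genes. The smooth muscle median is -0.56 for tip minus stalk, 0.35 for Wnt1 minus control culture and 2.01 for control culture minus stalk.

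In all, 4179 of 16112 genes differed between control culture and uncultured stalk (limma, adjusted p under 0.05), 2712 of them higher and 1467 lower in culture. The 10 with the largest rise were Tagln, Clec4d, Lgals3, Acta2, Ankrd1, S100a6, Gpnmb, Acer2, Wbp2nl and Saa3, with log2 fold changes from 5.40 to 4.03. The 10 with the largest fall were Klhl4, Hemgn, Ptch1, Hsd11b2, Sox17, Tmem204, Mycn, Sox18, Irs1 and Aplnr, from -4.34 to -3.24. Another probe set of the same gene moved the opposite way for Acer2, Klhl4, Ptch1, Mycn and Aplnr. In 668 of the higher genes even the brighter group lay under the highest array median, against 23 of the lower ones. The split into 64.9% higher depended on scaling, being 45.0% with quantile normalization (1196 genes) and 12.1% with array medians centred (3681 genes). With the signal floor, 701 genes passed, 596 of them among the 4179. Without stalk replicate 1 or 2 the count was 103 or 53, without control replicate 1 it was 786, without tip replicate 1 or 2 it was 2224 or 2228, and without Wnt1 replicate 2 it was 6283. Culture and any separate labelling or hybridisation of the culture arrays cannot be told apart in this design.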

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

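The tests of both patterns weighed in this part were chosen after the results were seen.

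Signals outside the comparisons by gene were found in 2 places. Of 7285 probe sets without a gene name, 2176 (29.9%) differed between control culture and uncultured stalk, 2078 higher and 98 lower. Of the probe sets with 1 symbol, 21.5% differed. No signal floor was applied to the unnamed probe sets. Changes of their transcripts therefore cannot be told apart from the raised noise floor weighed below. The hybridisation controls of the culture arrays reached 10.8 times the mean of the uncultured arrays, and 2.78 times on the culture array with the lowest value.

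The excess of higher calls in control culture over uncultured stalk, 64.9% of 4179 genes, is consistent with a raised noise floor on dim arrays that were scaled up. With values under the highest array median raised to it, 41.2% of the called genes were higher. An excess of truly raised genes remains open, because 58.6% were higher among called genes whose brighter group lay above that median, against 45.0% with quantile normalization and 12.1% with centred medians, and each scaling fixes where the middle of the genes lies.

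The rise of smooth muscle contractile genes in control culture is argued against as a product of the noise floor alone. With the signal floor, the list median was still 1.11 on the log2 scale (adjusted p = 0.00062), though without the floor the call was lost with an estimated correlation (adjusted p = 0.41), which was not run with the floor. Among single genes, Acta2 at 4.61, Actg2 at 3.97 and Tagln at 4.97 passed with the floor (adjusted p = 0.037, 0.027 and 0.026). A larger share of smooth muscle cells in the cultured pieces cannot be told apart from a change within cells. Over all 14 other members the median was 1.74 against 4.61 for Acta2, and over the 8 with a mean under 500 in stalk, chosen after that result, it was 2.38, below the limit of 2.56 set from the standard errors. Neither decides against a larger share as the whole change. With Acta2 at its value without _x_at and _s_at probe sets, 2.53, the limit was 0.029, and 2.38 lay above it. A filter on signal above the floor, tried in between, gave 2.65 and no exclusion, but it removed only Smtn, which had not risen, and so depended on the outcome and is void. The explanation is left open for a reason also added after these results: Acta2 was at 2.53 without _x_at and _s_at probe sets. In stalk, 7 of the 8 members lay under the highest array median, which is that of a culture array. The stalk arrays had medians of 95.5 and 76.5 (replicates 1 and 2). Only Myh11 and Lmod1 had stalk means, 84.4 and 48.0, that did not exceed both. The floor therefore does not show that the other members were poorly measured in stalk. Separate labelling or hybridisation of the culture arrays also stays open, since every culture array had hybridisation controls at least 2.78 times the uncultured mean. The effect of culture itself, which the design names, remains among the open explanations.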

How the results depend on the processing

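The signal floor, the fit without both culture arrays numbered 1, and the array quality weights were chosen after the data were seen. For each change below, the cause was not tested.

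Between tip and stalk, 0 genes passed in 25 of 26 alternatives, and 1, lower, with the signal floor. Between Wnt1 and control culture, 1 gene passed with the smaller pseudocount, with the mean of a gene's probe sets, with the replicate block and at an adjusted p under 0.10, 56 with the signal floor (9 higher, 47 lower) and 799 without both culture arrays numbered 1, where the spread came from uncultured arrays alone. Leaving out 1 array gave 0 to 56. Between control culture and stalk, the count was 1196 with quantile normalization, 8686 with probe sets taken singly, 6413 at an adjusted p under 0.10, 7045 without both culture arrays numbered 1, 701 with the signal floor, and 53 to 6283 when 1 array was left out. The lone array left in a group was assumed to vary like the other groups.

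The median log2 fold change of all genes in that comparison was 0.43, and -0.57 with array medians centred. Of the lists not called, 7 of 13 in tip minus stalk, 7 of 19 in Wnt1 minus control culture and 5 of 12 in control culture minus stalk passed in at least 1 alternative. All 8 lists called in the last kept their direction under both scalings. The correlation of the tip-stalk and Wnt1 fold changes was 0.087 with the signal floor and -0.072 to 0.10 when 1 array was left out. The Wnt1 response of stalk-high genes passed an unadjusted camera test with the 60th percentile filter (-0.32) and without control replicate 1 (-0.35), and ran from -0.39 to -0.0079 when 1 array was left out, but was 0.073 with quantile normalization. That of tip-high genes ran from -0.48 to 0.34, and passed at 0.31 without control replicate 1 and at 0.34 without Wnt1 replicate 2. Taking the 100 genes of smallest p at 2-fold for these sets equals the reported choice, and the robust variance model does not enter list tests, so neither gave a separate value.

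Signs turned for Rspo2 (0.23), Meis1 (0.41) and Tcf21 (0.13) with the mean of probe sets, and for Epcam (-0.58) and Hbb-y (-0.80) without _x_at and _s_at probe sets. Among named genes that did not pass, Acta2 turned from -1.24 to 0.90 in tip minus stalk and from 0.27 to -1.28 in Wnt1 minus control culture without those probe sets. In the latter comparison Myh11 turned from 0.14 to -0.54 with the signal floor. The immediate early and stress list turned to 0.48 without tip replicate 2 and 0.71 without stalk replicate 2 in tip minus stalk, with -1.29 as the lowest, without stalk replicate 1. In control culture minus stalk it ran from -0.71 without stalk replicate 1 to 1.19 without stalk replicate 2, and passed in both. Of the 20 genes with the largest changes in culture, all kept their direction wherever tested; 9 passed with the signal floor and 12 without stalk replicate 2. Of all 82 named calls in that comparison, 28 passed with the signal floor, 21 without stalk replicate 1 and 20 without stalk replicate 2.

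Replicate numbers are shared between groups, but deviations of same-numbered arrays correlated at -0.086 for tip and stalk at 0.30 for the culture groups, and at 0.14 for stalk with either culture group. The culture arrays numbered 1 also had brighter hybridisation controls (10.8 and 8.06) than those numbered 2 (3.56 and 2.78). Their medians went the same way, 299 and 296 against 209 and 149 (control and Wnt1 culture). With only 2 pairs, whether the numbers are batches is open, and they were not taken as pairs. With the replicate block, 0, 1 and 5352 genes passed in the 3 comparisons. That block spanned all 4 groups, and a pairing within the culture groups alone was not tried.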

Other observations

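The tests of the 5 added gene lists were fixed before their results were seen, but after the other results. The tests of the stress gene pattern were chosen after it was seen.

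Interferon response genes were higher in control culture than in uncultured stalk, with 5 of 11 members past the threshold and a list median 1.12 above that of all genes (camera, adjusted p = 0.0034 over the 5 lists). The call was lost with the signal floor (adjusted p = 0.090) and with an estimated correlation (adjusted p = 0.12), so a response to culture and a raised noise floor may both account for it. P53 targets lay 0.65 above all genes (adjusted p = 0.26), with 4 of 12 past the threshold, and genes of the unfolded protein and amino acid response 0.11 above (adjusted p = 0.84). Cholesterol synthesis genes lay at -0.042 from all genes and glucocorticoid-induced genes at -0.56 (camera, adjusted p = 0.91 for both), so these tests gave no call. Members of these lists passed all the same. Of 12 glucocorticoid-induced genes 4 were higher and 1 lower, of 11 cholesterol synthesis genes 1 was higher. Of 13 genes of the unfolded protein and amino acid response 3 were higher. Between Wnt1 and control culture, for which nothing was predicted, cholesterol synthesis genes had a median of -0.40 (adjusted p = 0.048, 0.0082 with the signal floor and 0.35 with an estimated correlation). Genes of the unfolded protein and amino acid response had a median of 0.30 (adjusted p = 0.048, 0.050 with the signal floor and 0.35 with an estimated correlation).

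Heat shock and immediate early genes split the uncultured arrays across the groups. Hspa1a had signals of 29492 and 707 in tip and of 498 and 14845 in stalk (replicates 1 and 2), and Fos of 3782, 278, 247 and 7194 in the same order. Of the 18 list members, 17 were higher on both tip replicate 1 and stalk replicate 2 than on both other arrays. These arrays were picked from the same genes, which are regulated together, so the count of 17 describes the split and does not test its cause. Handling shared by these arrays stays open, as the labels give no handling batch. Array brightness is argued against for tip replicate 1 only. Its hybridisation controls were 1.16 times the uncultured mean, within the 1.12 to 1.17 of the other pair. For stalk replicate 2 the controls do not decide, as it had the lowest value, 0.558. Its log2 difference from stalk replicate 1 had an SD of 0.487 over all genes, far below the differences of Hspa1a and Fos. These 2 genes were picked from the pattern, however, so that does not exclude brightness. No biological explanation was tested.

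Sex-linked genes also differed between arrays. Xist, expressed from the inactive X chromosome, had signals of 991 and 4379 in tip and 7275 and 5972 in stalk (replicates 1 and 2). The Y-linked Eif2s3y had signals of 2200 and 263 in tip and 594 and 722 in stalk. Xist was at 1477 and 906 in control culture and at 150 and 1299 with Wnt1. Eif2s3y was at 720 and 843 in control culture and at 595 and 366 with Wnt1. Sex was not a covariate, so its part in any of the 3 comparisons was not tested.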
